A study of Bos taurus with 30 samples.

How the data were processed

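DNA methylation was measured by reduced representation bisulfite sequencing in 30 libraries of bovine gametes and in vivo embryos, 3 per group in 10 groups. Per the labels, reads were trimmed with Trim Galore, aligned to UMD3.1/bosTau8 and called with Bismark 0.16.3, and Picard was used in a role that is not stated. Neither the deduplication nor any coverage minimum is stated. The deposited file of each library gives, per the file headers, the counts of total, methylated and unmethylated reads for each CpG cytosine on each strand, and the authors also gave the methylation rate as a fraction of methylated reads. In every file the methylated and unmethylated counts summed to the total, and the deposited fraction matched their ratio to within 1e-05. The reads themselves were not used here.

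Groups were taken from the titles and tissue labels. The analysis choices were fixed before the data were examined, except where stated. Sequencing lanes, 4 in all, appear only in file names. Replicate numbers were not treated as pairs, since over 37729 shared tiles the residuals of libraries with the same number had a mean correlation of -0.0082 over 109 pairs, against 0.0043 over the other 218 pairs, and 3 of the former exceeded 0.1. CpG sites of at least 5 reads on the 29 autosomes and the X were used, and libraries with fewer than 100000 such sites were left out (In vivo MII oocyte 2, 4-cell 3 and Blastocyst 3), which left 27. Mitochondrial and unplaced sequence was kept apart. The kept libraries held 291497 to 4826992 such sites, and with a median of 5 reads per site in sperm the level of a single site is coarse, so tests were made on regions.

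The overall level of a library was the unweighted mean over its CpG sites. Levels were compared by two-sided exact permutation tests of the difference of means, with Benjamini-Hochberg adjustment within 3 broad contrasts and within the 9 pairs, and over all groups by a permutation test of the F statistic with 100000 resamples. The smallest possible exact p was 0.00606 for oocytes against sperm, 0.000155 for the other broad contrasts and 0.1 for the pairs. Shared tiles were the 37729 tiles measured in at least 80% of the kept libraries.

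For the regional test, calls were summed over 300 bp tiles with at least 2 CpG cytosines of 5 reads in a library, and a tile was tested where at least 2 libraries of each group were measured. A logistic model with quasi-binomial spread was fitted to all 27 libraries, the spread was shrunk by the empirical Bayes method of limma (squeezeVar, with a floor of 1), and each group difference was tested by an F test with Benjamini-Hochberg adjustment over tiles. A tile was called at an adjusted p below 0.05 and a difference of at least 25 points between group means. The test was checked on simulated data with 200 changed tiles among 30000, where every group had the same spread at a tile. The named tiles are by a fixed rule among the 5 largest rises and the 5 largest falls of a comparison in called tiles whose library ranges do not overlap, with ties ordered by adjusted p and then position, and the text names the first 2 of each. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups.

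Gamete classes held tiles with a mean of at least 75% in one gamete and at most 25% in the other. Agreement between strands was measured on CpG pairs with at least 10 reads on each strand, thinned to 10 reads, and an MspI site was a pair read as CGG on both strands. The share of intermediate sites was that of sites whose 10 thinned reads gave a level from 20% to 80%. Shares of mitochondrial calls carry Wilson intervals at 95%.

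The alternatives tried were coverage minimums of 1 and 10 reads, tiles of 100 bp, no minimum difference, limma on tile percentages, a fit on the 2 groups alone, inclusion of all libraries, a mean weighted by reads, shared tiles alone, other class limits, the replicate number as a block, and leaving out each library. Further alternatives were chosen after seeing the data: leaving out CpGs on MspI sites, a lane term, leaving out Early morula 1, Early morula 2 and Compact morula 3, alone or with Compact morula 1, and the replicate block for the gamete classes, which had been planned for the other results only. The gene table at hand is on another assembly than the calls, so promoters, gene lists and feature classes that had been planned were not analysed and tiles are given by position. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.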

Results

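Bovine sperm, oocytes and preimplantation embryos were profiled by reduced representation bisulfite sequencing, which cuts DNA with the enzyme MspI and reads the methylation of CpG-rich fragments base by base. The 30 libraries formed 10 groups of 3: sperm, immature oocytes, oocytes matured in vitro to metaphase II (in vitro MII), oocytes matured in the cow to metaphase II (in vivo MII), and embryos at the 2-cell, 4-cell, 8-cell, early morula, compact morula and blastocyst stages. Per the labels, individual gametes or embryos were lysed in single tubes, sperm was frozen semen of a bull of proven fertility, immature and in vitro matured oocytes came from slaughterhouse ovaries, and in vivo oocytes and embryos were flushed from superovulated cows, of which 10 are mentioned. The libraries titled 8-cell carry the source name 16-cell and were kept under their title. No label states that the libraries of a group came from separate animals, so every p-value measures the spread between these libraries only.

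Depth differed widely between the libraries. The 27 libraries compared held between 383550 (In vitro MII oocyte 3) and 7140045 (8-cell 3) CpG cytosines of nuclear DNA and between 23559272 and 118890848 calls of methylated or unmethylated. The CpG sites read at least 5 times numbered between 291497 and 4826992, and the median reads per site lay between 5 in sperm and 65 in In vitro MII oocyte 1. In vivo MII oocyte 2, 4-cell 3 and Blastocyst 3 had 18738, 81074 and 2599 such sites and were left out of the comparisons, so those groups rest on 2 libraries each. PCR reads without molecular identifiers are not independent molecules, and intervals from read counts cover counting error only. The spread of methylation between pairs of sperm libraries was 1.23 to 1.35 times that of read sampling, against 3.83 to 109 times in the pairs of every other group, so the sperm libraries varied little more than repeated draws from 1 pool.

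The first question was how the overall methylation level moved from gametes to blastocysts. The mean level over CpG sites of at least 5 reads was 28.6% ± 0.635 (SD, n = 3) in sperm, 29.3% ± 1.24 (n = 3) in immature oocytes, 28.4% ± 1.6 (n = 3) in in vitro MII oocytes and 35.1% ± 6.99 (n = 2) in in vivo MII oocytes. It was 23.3% ± 3.17 (n = 3) at the 2-cell stage, 30.8% ± 3.61 (n = 2) at the 4-cell stage and 15.7% ± 1.24 (n = 3) at the 8-cell stage. It then stood at 24.6% ± 7.24 (n = 3) in early morulae, 26.7% ± 0.595 (n = 3) in compact morulae and 15.3% ± 1.96 (n = 2) in blastocysts. Over 37729 tiles of 300 bp measured in most libraries, which hold the set of positions nearly fixed, the 8-cell stage (11.2% ± 0.187, n = 3) and the blastocyst (10.9% ± 0.977, n = 2) were again the lowest groups, and the mean was 27.6% ± 7.59 (n = 2) in in vivo MII oocytes and 26.6% ± 0.0334 (n = 3) in sperm.

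The 10 groups differed in level by more than the spread between libraries (F 7.95, permutation p 0.0002, 100000 resamples, where the smallest possible p is 1e-05). Embryos of the 2-cell to 8-cell stages lay below oocytes, with a difference of -8.07 points, an exact two-sided permutation p of 0.0134 and an adjusted p of 0.0401 over 3 contrasts, and 7 of the 8 embryo libraries lay below the oocyte mean. This call rests on single libraries. The adjusted p rose above 0.05 without 8-cell 1 (0.0821), 8-cell 2 (0.0797), 8-cell 3 (0.0793), In vivo MII oocyte 1 (0.0741), 2-cell 3 (0.0727) or 2-cell 2 (0.0723). It also did so without Immature oocyte 2 (0.0541), In vivo MII oocyte 3 (0.0536), In vitro MII oocyte 1 (0.0536) or Immature oocyte 1 (0.0527). Over all libraries left out in turn, those that kept the call included, the difference stayed between -9.64 and -6.70 points. Oocytes and sperm differed by 1.79 points (exact p 0.503, adjusted 0.755), but the setting decided both the sign and the call. The difference was -8.56 points at a minimum of 1 read (adjusted exact p 0.0364, 7 of 8 oocyte libraries below the sperm mean), 9.70 points at 10 reads (0.0182, 8 of 8 above) and 10.8 points weighted by reads (0.00909, 8 of 8 above). The sperm mean was 40.3% at 1 read and 19.9% at 10 reads. Morulae and blastocysts differed from 2-cell to 8-cell embryos by 0.695 points (exact p 0.831, adjusted 0.831), a value that turned to -0.455, -0.180, -0.125 or -0.274 points without 8-cell 1, 8-cell 2, 8-cell 3 or Early morula 2. Lane numbers in the file names put few of these groups side by side. In lane 2, 8-cell 3 stood at 16.6% against 27.2% to 30.3% in 5 oocyte libraries, in lane 1 sperm lay at 28.1% to 29.3% and oocytes at 27.8%, 30.1% and 40.0%, and in lane 4, 8-cell 1 stood at 14.3% against 13.9% to 27.0% in 6 morula and blastocyst libraries. Each of the 9 pairs of groups has too few libraries for an exact p below 0.1, so their differences are given as values within each comparison.

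**Figure D1:**
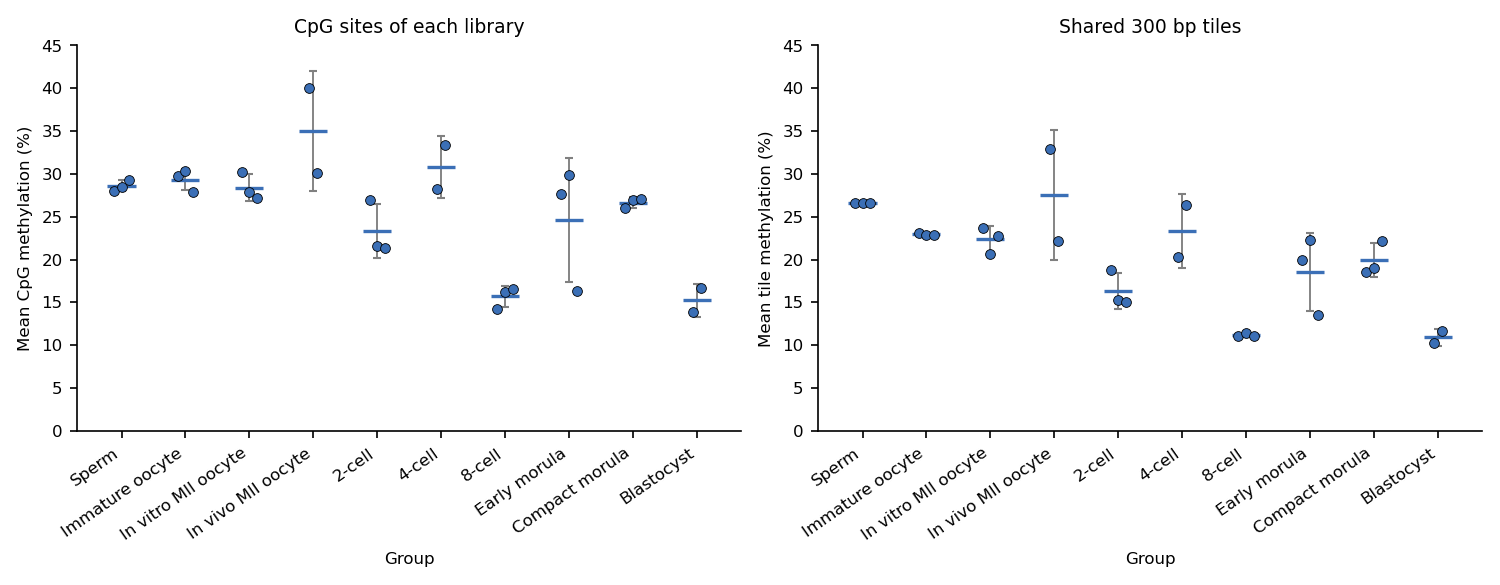
Mean CpG methylation in percent by group, over the CpG sites of each library on the left and over shared 300 bp tiles on the right. Points are libraries, lines are group means and bars are SD; on the left the 8-cell mean of 15.7% and the blastocyst mean of 15.3% are the lowest.

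A further question was what became of the methylation that each gamete brought. Tiles methylated in sperm and not in in vivo MII oocytes (at least 75% in the former and at most 25% in the latter) numbered 3857, and tiles with the opposite pattern numbered 1714. Sperm-methylated tiles stood at 82.4% ± 0.0687 (n = 3) in sperm, then at 22% ± 3.60 (n = 3) in 2-cell, 29.5% ± 7.42 (n = 2) in 4-cell and 11.7% ± 0.638 (n = 3) in 8-cell embryos. Oocyte-methylated tiles stood at 85.0% ± 3.23 (n = 2) in in vivo MII oocytes, then at 40.4% ± 7.37 (n = 3), 55.6% ± 5.53 (n = 2) and 32.8% ± 1.85 (n = 3) at those stages. An embryo holds both genomes. In vivo MII oocytes stood at 13.75% in the sperm class and sperm at 10.1% in the oocyte class. An embryo level below that of 1 gamete can thus reflect mixing of the genomes as well as loss. The gamete libraries are also high or low in these classes by selection, since they set them. Tiles methylated in both gametes (9007) fell from 84.1% in in vivo MII oocytes to 40.4% ± 2.91 (n = 3) at the 8-cell stage, while tiles methylated in neither (37737) stayed between 3.0% and 5.3% in every group.

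Morula libraries of the same stage differed widely in these tiles. The oocyte-methylated class averaged 61.4% ± 25.3 (n = 3) in early morulae, 51.9% ± 26.2 (n = 3) in compact morulae and 29.7% ± 4.75 (n = 2) in blastocysts, and the sperm-methylated class averaged 10.8% ± 3.53, 24.3% ± 14.5 and 15.1% ± 0.862. Early morula 1, Early morula 2 and Compact morula 3 kept 73.5%, 78.3% and 78.5% in the oocyte class and 9.46%, 8.12% and 9.59% in the sperm class, near the immature oocytes at 79.2% and 12.3%. Early morula 3 had 32.3% and 14.8%, and Compact morula 1 had 26.1% and 38.6%. Sperm class minus oocyte class was -21.4 ± 4.03 points (n = 8) in 2-cell to 8-cell libraries and -32.9 ± 30.9 (n = 8) in morulae and blastocysts, a difference of -11.6 points with an exact two-sided permutation p of 0.296. It was -18.1 points without Compact morula 1, and -6.24, -6.43, -7.13 and -2.01 points without Early morula 2, Compact morula 3, Early morula 1 or In vivo MII oocyte 3. Without Early morula 1, Early morula 2 and Compact morula 3 together it was 9.30 points (exact permutation p 0.0676), and 3.16 points (exact permutation p 0.293) without Compact morula 1 as well.

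**Figure D2:**
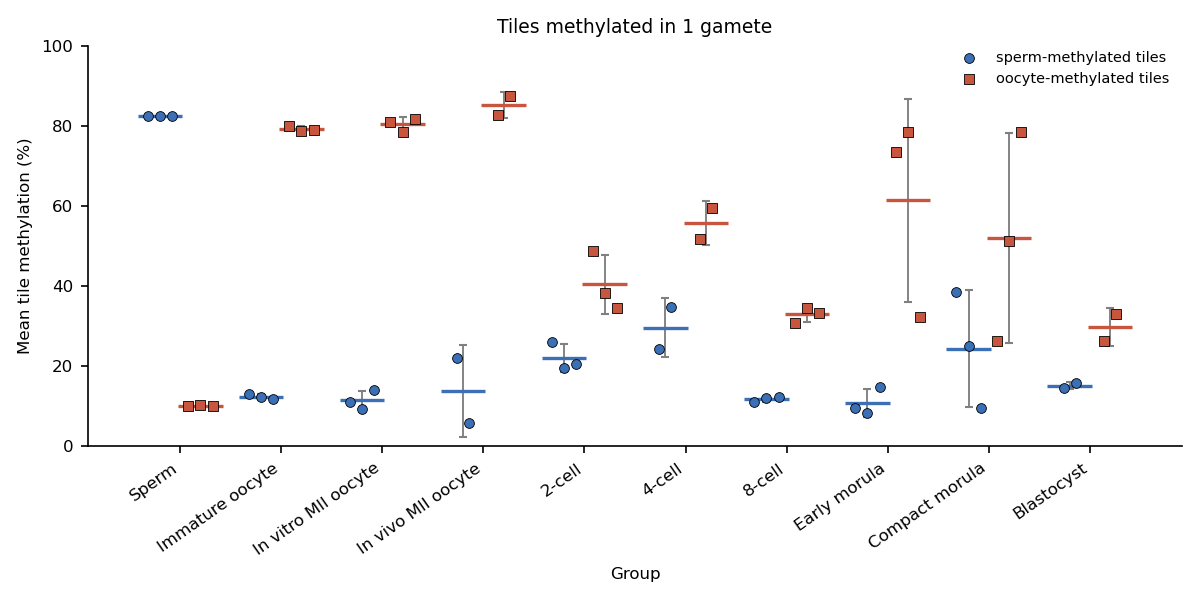
Mean methylation in percent of tiles methylated in sperm only and of tiles methylated in in vivo MII oocytes only, by group, with points for libraries, lines for group means and bars for SD. Both classes are low at the 8-cell stage (11.7% and 32.8%), and the oocyte class spreads widely in early morulae (61.4% ± 25.3).

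Differences at single regions were then tested in 9 pairs of groups. Tiles of 300 bp were called different at an adjusted p below 0.05 and a difference of at least 25 points, in 1 logistic fit of all 27 libraries. In these comparisons the gamete classes were set on sperm and all 3 oocyte groups, which gave 10246 sperm-methylated, 1960 oocyte-methylated and 9365 tiles methylated in both. In data simulated with known changes, the test found 24% to 34% of changes of 30 points and 78% to 90% of changes of 90 points, so moderate changes were often missed. Among unchanged simulated tiles it made 1 false call for In vivo MII oocyte against Sperm, 51 for 8-cell against 4-cell and 57 for Early morula against 8-cell, or 0.00336%, 0.171% and 0.191%. With 200 changed tiles among 30000, false calls made up 0.926%, 30.5% and 33.1% of all calls. Error in the simulated embryo comparisons thus exceeded the nominal rate. In these simulations every group had the same spread at a tile. In the data, replicate pairs spread 3.83 to 4.68 times read sampling at the 8-cell stage and 47.9 times at the 4-cell stage. Early morula pairs reached 109 times. Neither the false-call rate nor the share of changes found was tested under such unequal spread. The calls rest on the spread shared by the 10 groups. Fitted on its 2 groups alone, the same logistic test called 0 tiles for In vivo MII oocyte against Immature oocyte, In vitro MII oocyte against In vivo MII oocyte, 2-cell against In vivo MII oocyte, 4-cell against 2-cell, Compact morula against Early morula and Blastocyst against Compact morula, with 7906, 4872, 14612, 13433, 4711 and 15031 tiles at an unadjusted p below 0.05 in that order, while limma on tile percentages called 258, 185, 5793, 1963, 217 and 2287. For Early morula against 8-cell such a fit gave 18 tiles. Of the 90 tiles that the naming rule picked over the 9 comparisons, 71 lost their call in the fit on the 2 groups alone, where the 19 left belonged to In vivo MII oocyte against Sperm and 8-cell against 4-cell, and 64 lost it with a lane term.

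**Figure D3:**
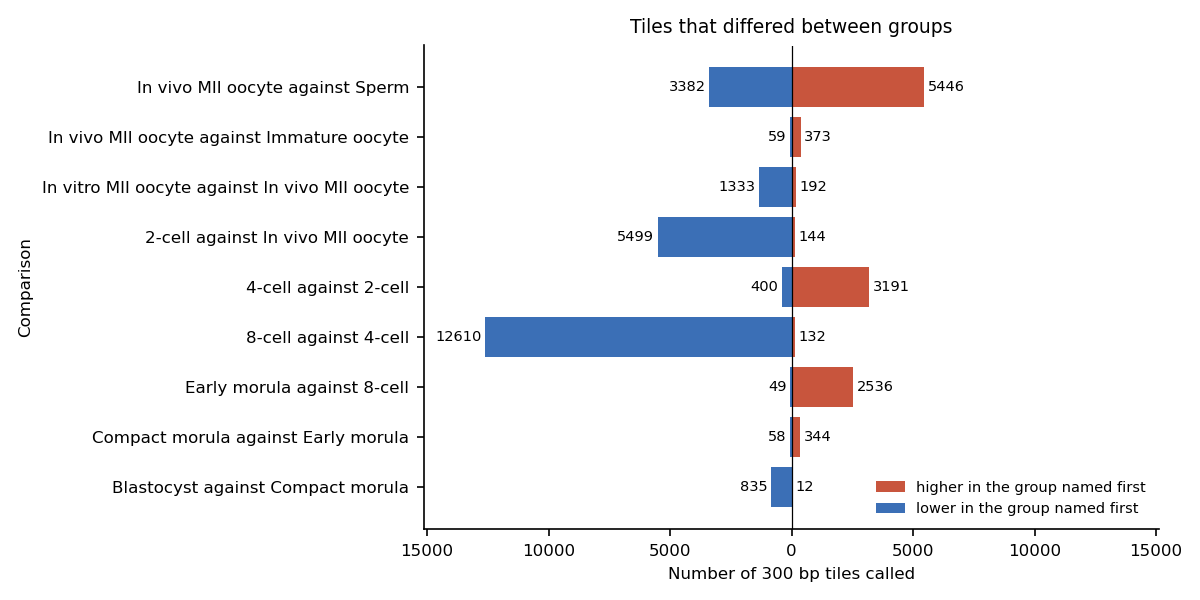
Number of 300 bp tiles called higher or lower in the later group of each of 9 comparisons, as horizontal bars. The longest bar is the 12610 tiles lower at the 8-cell than at the 4-cell stage.

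The gametes themselves were compared first. In vivo MII oocytes were more methylated than sperm where CpGs were dense and less methylated where they were sparse. In tiles of at least 20 CpGs the mean went from 13.4% in sperm to 18.7% in oocytes with 2149 rises and 323 falls, and in tiles of 2 to 5 CpGs from 56.2% to 41.9% with 185 rises and 423 falls. Of 107644 tiles, 5446 were higher and 3382 lower in oocytes (limma 6556 and 7666). Chromosome 20, 65653801 to 65654100, had the largest rise, from 1.24% ± 1.17 (n = 3) to 100% ± 0.0 (n = 2; adjusted p 0.014), a call that ended without In vivo MII oocyte 3. Chromosome X, 147554101 to 147554400, had the next largest, from 1.92% ± 1.03 (n = 3) to 100% ± 0.0 (n = 2; adjusted p 0.000357). Chromosome 29, 49879501 to 49879800 (n = 3 and 2; adjusted p 0.00471) and chromosome 21, 65583601 to 65583900 (n = 2 and 2; adjusted p 0.0112) had the largest falls, both from 100% to 0.0% in all measured libraries. Without Sperm 1, Sperm 2 or Sperm 3 the count of 8828 became 4437, 4224 or 4107, and without In vivo MII oocyte 1 it became 12744, with 3337 rises and 9407 falls. Both groups lay in lane 1 (level difference 6.42 points, exact p 0.1), and without In vivo MII oocyte 1 or 3 that difference was 1.48 or 11.4 points.

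Maturation in the cow was examined by setting in vivo MII oocytes against immature oocytes. Few tiles were called, and these were mainly gains. Of 74518 tiles, 373 were higher and 59 lower after maturation (limma 209 and 49). Tiles methylated in sperm and not in oocytes went from 7.53% to 29.5%, with 82 rises and 0 falls by the logistic test among 5832, and that gain came from In vivo MII oocyte 1, at 50.7% against 7.54% in In vivo MII oocyte 3. It also depends on the oocytes that set the class, which are low in it by selection. In the class set on sperm and in vivo MII oocytes, immature oocytes stood at 12.3% and in vivo MII oocytes at 13.75%. Chromosome 4, 79757401 to 79757700, had the largest rise, from 0.0% ± 0.0 to 96.8% ± 4.48 (n = 2 and 2; adjusted p 0.0166). Chromosome 24, 22002001 to 22002300, had the next largest, from 2.49% ± 2.52 (n = 3) to 91.2% ± 7.82 (n = 2; adjusted p 0.0211). Chromosome 10, 102886801 to 102887100, had the largest fall, from 99.4% ± 0.108 to 6.22% ± 8.79 (n = 2 and 2; adjusted p 0.00878). Chromosome 22, 59487001 to 59487300, had the next largest, from 91.3% ± 8.31 (n = 3) to 0.0% ± 0.0 (n = 2; adjusted p 0.0474). The count of 432 became 39 without In vivo MII oocyte 1, which ended 3 of these 4 calls, 8221 without In vivo MII oocyte 3, and 251, 73 or 158 without Immature oocyte 1, 2 or 3, of which each ended the call on chromosome 22 and the second also that on chromosome 24. The groups shared no lane, a lane term resting on the other groups left 7 tiles, and the level difference of 5.71 points (exact p 0.2) was 0.770 without In vivo MII oocyte 1 and 10.7 without In vivo MII oocyte 3.

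Maturation in culture was then set against maturation in the cow. Oocytes matured in vitro were lower than those matured in vivo at most of the tiles called. In tiles methylated in sperm and not in oocytes the mean went from 30.8% to 6.04%, with 382 falls and 1 rise among 2588, and in tiles methylated in oocytes and not in sperm from 77.3% to 86.4%. Both differences came from In vivo MII oocyte 1, at 50.7% and 73.4% in these classes, since In vivo MII oocyte 3 stood at 7.54% and 85.6%. They also depend on the oocytes that set the classes, which are high or low in them by selection. In the classes set on sperm and in vivo MII oocytes, the sperm class stood at 13.75% in vivo and 11.4% in vitro. The oocyte class there stood at 85.0% and 80.4%, the opposite direction. Of 35707 tiles, 192 were higher and 1333 lower after maturation in vitro (limma 39 and 146). Chromosome 5, 117805201 to 117805500, had the largest rise, from 0.0% ± 0.0 to 90.6% ± 0.15 (n = 2 and 2; adjusted p 0.00645). Chromosome 3, 98060401 to 98060700, had the next largest, from 8.07% ± 10.3 to 95.9% ± 5.83 (n = 2 and 2; adjusted p 0.00167). Chromosome 13, 11731801 to 11732100, had the largest fall, from 96.8% ± 4.58 to 0.0% ± 0.0 (n = 2 and 2; adjusted p 0.00785). Chromosome 5, 84079801 to 84080100, had the next largest, from 96.6% ± 4.75 to 0.077% ± 0.109 (n = 2 and 2; adjusted p 0.000687). Without In vivo MII oocyte 1 the count of 1525 became 153 and the first rise and first fall named were no longer called, and it became 5803, 448 or 289 without In vivo MII oocyte 3, In vitro MII oocyte 1 or In vitro MII oocyte 2. A lane term left 348 tiles, and the level difference of -6.65 points (exact p 0.2) was -7.21 within lane 1, -1.71 without In vivo MII oocyte 1 and -11.6 without In vivo MII oocyte 3.

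The first cleavage was followed by comparing 2-cell embryos with in vivo MII oocytes. Nearly all called tiles were lower in 2-cell embryos. Tiles methylated in oocytes and not in sperm went from 79.1% to 42.1% (171 called falls among 1297). Sperm stood at 9.80% in this class, so the sperm genome that joins at fertilization can lower it without any loss. Such mixing was not told apart from loss. Tiles methylated in both gametes, which mixing alone would lower little, fell from 80.5% to 56.1% (346 among 5838). Tiles methylated in sperm and not in oocytes had 143 falls and 32 rises among 6651, from 29.3% to 20.5%, but their starting level was 50.7% in In vivo MII oocyte 1 and 7.54% in In vivo MII oocyte 3, so against the latter 2-cell embryos were higher. Of 110758 tiles, 144 were higher and 5499 lower in 2-cell embryos (limma 210 and 5583). Chromosome 8, 7781701 to 7782000, had the largest rise, from 0.0% to 100% (n = 2 and 2; adjusted p 0.0463), a call that ended without In vivo MII oocyte 1 or 3. Chromosome 29, 50794201 to 50794500, had the next largest, from 0.0% ± 0.0 to 98.96% ± 1.47 (n = 2 and 2; adjusted p 0.00217). Chromosome 22, 54194401 to 54194700 (adjusted p 0.00259) and chromosome 14, 475201 to 475500 (adjusted p 0.00422) had the largest falls, both from 100% to 0.0% in all measured libraries (n = 2 and 2). The count of 5643 became 797 without In vivo MII oocyte 1, 15110 without In vivo MII oocyte 3, 3750 without 2-cell 2 and 3182 without 2-cell 3. No lane held both groups, a lane term resting on the other groups left 1 tile, and the level difference of -11.7 points (exact p 0.1) was -6.76 without In vivo MII oocyte 1 and -16.6 without In vivo MII oocyte 3.

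From the 2-cell to the 4-cell stage the called changes were mostly gains, in every class of tile. Tiles methylated in sperm and not in oocytes went from 20.6% to 30.4% (306 rises and 48 falls among 5656), tiles of the oocyte class from 42.3% to 56.2% (71 and 13 among 1118), and tiles methylated in both gametes from 55.7% to 71.5% (274 and 13 among 4406). The gain differed by library. In these classes 2-cell 1 stood at 24.3%, 51.4% and 68.4%, close to 4-cell 1 at 23.3%, 54.0% and 69.9%. By contrast, 2-cell 2 stood at 18.9%, 39.8% and 51.5%, and 2-cell 3 at 19.2%, 36.1% and 50.9%. The highest levels were those of 4-cell 2, at 37.6%, 59.55% and 73.2%. Of 101077 tiles, 3191 were higher and 400 lower at the 4-cell stage (limma 1748 and 215). Chromosome 13, 3834001 to 3834300 (n = 3 and 2; adjusted p 0.00048) and chromosome 18, 8357701 to 8358000 (n = 2 and 2; adjusted p 0.00208) had the largest rises, both from 0.0% to 100% in all measured libraries. The largest falls lay at chromosome 18, 10197901 to 10198200 (adjusted p 0.00705) and chromosome 26, 17809201 to 17809500 (adjusted p 0.034), both from 100% to 0.0% (n = 2 and 2), and the call on chromosome 26 ended without 4-cell 2. The count of 3591 became 13152 without 4-cell 1, 2054 without 2-cell 2 and 1522 without 2-cell 3. All libraries of both groups lay in lane 3 (level difference 7.46 points, exact p 0.2), a lane term left 1901 tiles, the difference was 4.91 without 4-cell 2, and it turned to -0.269 with the thinly covered 4-cell 3 included.

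Embryos at the 8-cell stage were less methylated than 4-cell embryos at nearly all called tiles. The loss covered every class, with falls from 30.6% to 11.8% in sperm-methylated tiles, from 56.6% to 34.6% in oocyte-methylated tiles and from 71.6% to 42.1% in tiles methylated in both gametes. Of 124648 tiles, 132 were higher and 12610 lower at the 8-cell than at the 4-cell stage (limma 65 and 7408). At the false-call rate in simulated data, 213 false calls of both directions together fall on these tiles. That total exceeds the 132 rises, but false calls were not split by direction. Chromosome 9, 102026101 to 102026400, had the largest rise, from 0.0% ± 0.0 (n = 2) to 63.4% ± 24.0 (n = 3; adjusted p 0.00856). Chromosome 15, 48396001 to 48396300, had the next largest, from 0.0% ± 0.0 (n = 2) to 57.1% ± 9.73 (n = 3; adjusted p 0.0423). Chromosome 7, 20417401 to 20417700, had the largest fall, from 100% (n = 2) to 0.0% (n = 3; adjusted p 0.033). Chromosome 26, 48240301 to 48240600, had the next largest, from 100% ± 0.0 to 1.52% ± 2.14 (n = 2 and 2; adjusted p 0.0174). The count of 12742 became 31613 without 4-cell 1, 7025 without 8-cell 1, 6405 without 8-cell 2 and 3244 without 8-cell 3, and the 4 named calls were lost without 4-cell 1 (chromosome 9), any of the 5 libraries (chromosome 15), 4-cell 2 or any 8-cell library (chromosome 7) and 4-cell 2 (chromosome 26). Without 4-cell 1 the tiles tested rose from 124648 to 202830, and without 8-cell 3 they fell to 117420. The counts above thus rest on different sets of tiles. The level difference was -15.1 points (exact p 0.1) and -14.6 within lane 3, where 1 8-cell library lay, and a lane term left 195 tiles.

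Early morulae were compared with 8-cell embryos to follow methylation past the 8-cell stage. The called tiles were almost all higher in early morulae, and among the gamete classes they lay mainly in those methylated in oocytes. Oocyte-methylated tiles went from 34.7% to 58.6% (88 rises among 1243) and tiles methylated in both gametes from 42.2% to 61.9% (384 among 5264), while sperm-methylated tiles stood at 11.6% and 11.2% (16 among 5940). The gain was carried by Early morula 1 and 2, at 78.2% and 81.3% in the oocyte class and 77.0% and 79.1% in the class of both gametes, while Early morula 3 stood at 32.9% and 43.3%, near the 8-cell means of 34.5% and 42.0%. Of 125977 tiles, 2536 were higher and 49 lower, whereas limma called 73 higher and 0 lower, with 28807 tiles at an unadjusted p below 0.05 in the logistic test. At the false-call rate in simulated data, 241 false calls of both directions together fall on these tiles. That total exceeds the 49 falls, but false calls were not split by direction. Chromosome 28, 29091301 to 29091600, had the largest rise, from 5.21% ± 7.37 to 100% ± 0.0 (n = 2 and 2; adjusted p 0.0364). Chromosome 14, 24227701 to 24228000, had the next largest, from 9.89% ± 7.63 (n = 3) to 100% ± 0.0 (n = 2; adjusted p 0.0118). Chromosome 11, 80506801 to 80507100, had the largest fall, from 75.2% ± 4.85 to 15.8% ± 22.1 (n = 2 and 2; adjusted p 0.0103). Chromosome 19, 23176801 to 23177100, had the next largest, from 50.8% ± 19 (n = 3) to 0.203% ± 0.287 (n = 2; adjusted p 0.0474). The count of 2585 became 994, 612 or 135 without 8-cell 1, 8-cell 2 or 8-cell 3 and 1247, 1128 or 5273 without Early morula 1, 2 or 3, and the named calls were lost without 8-cell 1 (chromosome 28), 8-cell 3 (chromosome 14), and any 8-cell library or Early morula 2 (chromosome 19). The level difference of 8.91 points (exact p 0.2) was 12.1 within lane 2, with Early morula 1 and 2, and 2.05 within lane 4, with Early morula 3, a lane term left 1162 tiles, and without Early morula 1, Early morula 2 and Compact morula 3, which resembled oocytes in the gamete classes, 87 tiles and a level difference of 0.645 points were left.

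Compact morulae were compared with early morulae to follow compaction, and few tiles were called. Tiles methylated in sperm and not in oocytes went from 11.2% in early to 24.0% in compact morulae with 59 rises and 4 falls among 3742. The gain was carried by Compact morula 1 (39.5%) and Compact morula 2 (23.8%), while Compact morula 3 stood at 8.34%, within the early morula range of 7.42% to 14.8%. Across the shared tiles, which are not independent replicates, Compact morula 1 correlated most with sperm (mean r 0.643), above its own group (0.468) and the oocyte groups (0.440). Tiles methylated in both gametes went from 62.2% to 69.0%, and oocyte-methylated tiles from 59.3% to 53.4%. Of 62127 tiles, 344 were higher and 58 lower in compact morulae (limma 193 and 24), but without Early morula 3 the numbers were 239 and 197. Chromosome 10, 89131801 to 89132100, had the largest rise, from 0.654% ± 0.924 to 100% ± 0.0 (n = 2 and 2; adjusted p 0.00728). Chromosome 15, 66830401 to 66830700, had the next largest, from 0.0% ± 0.0 to 97.9% ± 2.95 (n = 2 and 2; adjusted p 0.0301). Chromosome 14, 24227701 to 24228000, had the largest fall, from 100% ± 0.0 (n = 2) to 11.5% ± 19.99 (n = 3; adjusted p 0.0344), which was also the tile with the second largest rise into early morulae. Chromosome 25, 1707601 to 1707900, had the next largest, from 79.4% ± 18.0 to 0.0% ± 0.0 (n = 2 and 2; adjusted p 0.0368). The count of 402 became 183 or 267 without Early morula 1 or 2 and 70 or 72 without Compact morula 1 or 2, and the call on chromosome 14 ended without Compact morula 1. The level difference of 2.06 points (exact p 1) was 10.3 within lane 4, where only Early morula 3 lay, 3.58 and 4.67 without Early morula 1 or 2, and -2.07 without Early morula 3, a lane term left 4 tiles, and without the 3 libraries that resembled oocytes 222 tiles and a level difference of 10.1 points were left.

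Blastocysts were compared with compact morulae to ask how methylation stood once the embryo formed a cavity. Blastocysts were lower at almost every called tile, and among the gamete classes the largest fall was in tiles methylated in both gametes, from 69.2% to 41.5% (127 falls among 3768). Oocyte-methylated tiles fell from 52.4% to 31% (22 among 975), and sperm-methylated tiles from 24.1% to 15.7% (23 falls and 2 rises among 5003). These 2 falls turned with the library. In the oocyte class Compact morula 1, 2 and 3 stood at 26.4%, 52.5% and 83.6%, against 26.8% and 34.9% in the blastocysts. In the sperm class they stood at 39.5%, 23.8% and 8.34%, against 14.9% and 16.2%. In tiles methylated in both gametes every compact morula (58.2% to 81.8%) lay above the blastocysts (37.5% and 44.5%). Mitochondrial DNA took 18.8% to 56.4% of calls in compact morulae and 0.490% and 0.914% in blastocysts. Whether such a difference between libraries bears on the level was not tested. Of 84349 tiles, 12 were higher and 835 lower in blastocysts (limma 28 and 2259). Chromosome 1, 147058501 to 147058800, had the largest rise, from 0.0% ± 0.0 to 59.5% ± 35.1 (n = 2 and 2; adjusted p 0.0305). Chromosome 22, 52011301 to 52011600, had the next largest, from 0.239% ± 0.338 to 52.6% ± 9.43 (n = 2 and 2; adjusted p 0.0195). Chromosome 5, 38593201 to 38593500, had the largest fall, from 100% to 0.0% (n = 2 and 2; adjusted p 0.0439). Chromosome 6, 106025101 to 106025400, had the next largest, from 100% ± 0.0 to 2.38% ± 3.37 (n = 2 and 2; adjusted p 0.047). The count of 847 became 1385 or 47 without Compact morula 1 or 3 and 3 or 396 without Blastocyst 1 or 2, and all 4 named calls ended without Blastocyst 1, the falls also without Blastocyst 2. Both groups lay in lane 4 (level difference -11.4 points, exact p 0.1), a lane term left 146 tiles, and 386 were left without the 3 morula libraries that resembled oocytes.

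The X chromosome and CpG density set further contrasts. Over shared tiles, the X stood at 12.8% ± 0.0523 (n = 3) in sperm against 26.9% on the autosomes, whereas immature oocytes had 25.8% against 22.9% and 8-cell embryos 9.99% against 11.2%. The X share of called tiles exceeded that of the autosomes most for In vivo MII oocyte against Sperm (11.9% against 8.13%) and 2-cell against In vivo MII oocyte (7.30% against 5.04%). By density, sperm went from 56.9% in tiles of 2 to 5 CpGs to 14.4% in tiles of at least 20, immature oocytes from 40.9% to 17.3%, and 8-cell embryos from 21.1% to 9.87%. No test was made of these values.

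Whether both strands of a CpG carried the same mark bears on how methylation is passed on when DNA is copied. Pairs of cytosines with at least 10 reads on each strand were thinned to 10 reads, and a pair was discordant when 1 strand was at least 80% methylated and the other at most 20%. Outside MspI sites, discordant pairs made up 0.182% of methylated pairs in sperm, 14.0% in immature, 12.6% in in vitro MII and 10.9% in in vivo MII oocytes. The share was 53.7% ± 7.37 (n = 3) in 2-cell, 37.3% (n = 2) in 4-cell and 6.65% ± 2.30 (n = 3) in 8-cell embryos, 18.4% ± 2.04 (n = 3) in early morulae, and 36.3% ± 22.6 (n = 3) in compact morulae. The 2 blastocysts had 49.8% and 3.97%. On MspI sites, which held 18.3% of the CpG pairs seen, the share was 65.6% in sperm and 80.2% to 87.4% in the other groups. No test was made, and lysates of 1 embryo hold few copies of each strand.

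**Figure D4:**
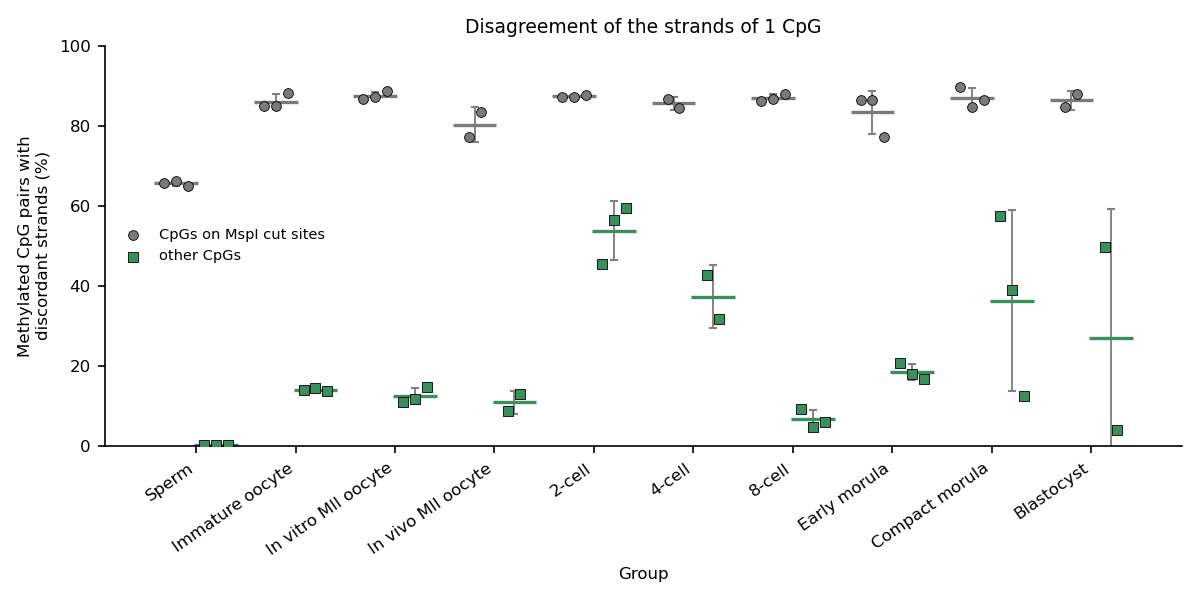
Discordant pairs as a percent of methylated CpG pairs, by group, at MspI sites and at other CpGs, with points for libraries. Away from MspI sites sperm is at 0.182% and 2-cell embryos are at 53.7%.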

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

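The tests of oocyte content, of a gain of methylation across the genome, of DNA from sperm or other cells, and of the strands were chosen after the result was seen, while those on the set of covered sites were chosen before. Some values lie in data outside the comparisons. The median over the kept libraries of methylated calls on mitochondrial DNA was 2.58%. With so many calls any incomplete conversion passes the limit that a count of 0 allows, so this value cannot tell mitochondrial methylation from incomplete conversion. CpG sites on unplaced sequence had a median share of 1.49%. The thinly covered libraries had levels of 12.1% in Blastocyst 3, 7.61% in 4-cell 3 and 28.5% in In vivo MII oocyte 2.

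Early morula 1, Early morula 2 and Compact morula 3 resembled oocytes, with mean levels of 73.5%, 78.3% and 78.5% in oocyte-methylated tiles of the classes set on sperm and in vivo MII oocytes. The set of covered sites is argued against by a smallest difference from Early morula 3 of 44.9 points over the same tiles, and a gain across the genome by sperm-class levels of at most 9.59%, against at least 10.96% (SD 0.638) in 8-cell embryos, or of at most 8.34% against 10.9% (SD 0.586) in the classes set on all oocyte groups. In 6 immature and in vitro MII oocyte libraries, strand discordance outside MspI sites was 11.1% to 14.8% (SD 1.5). Early morula 1 had 20.6%, and its oocyte-class level of 73.5% lay below their 78.5% to 81.7% (SD 1.30). Both values argue against an unchanged oocyte in its place. Early morula 2 had 18.0%, but its class levels of 78.3% and 8.12% lay within 1 SD of the ranges of these oocytes. An unchanged oocyte thus stays open for Early morula 2, where mitochondrial DNA took 69.1% of calls. Unfertilized oocytes flushed with embryos were not sampled and are not covered by this test. For Compact morula 3 the strand discordance outside MspI sites was 12.6%, and its class levels of 78.5% and 9.59% lay within 1 SD of the oocyte ranges of 78.5% to 81.7% and 9.32% to 14.0%, so an oocyte without a paternal genome in that tube stays open as a candidate explanation, as do embryos with maternal DNA alone, which were not tested. That rests on a range replaced after its result was seen: a first one, of 7 oocyte libraries in classes set on all oocyte groups, argued against it (83.6% against at least 85.6%), but those libraries had themselves set the classes and so were high by selection.

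In vivo MII oocyte 1 departed from the other oocytes, at 57.1% against 11.3% in In vivo MII oocyte 3 over the same 6611 sperm-methylated tiles, a difference of 45.8 points that argues against the set of covered sites. Sperm DNA in the tube as the whole cause is argued against by a level of 69.7% in 7668 tiles methylated in sperm and in immature and in vitro MII oocytes, where In vivo MII oocyte 3, which like it took no part in setting this class, had 81.3%. The libraries that set a class are high in it by selection, so the class was set again on Sperm 1, Sperm 2 and the immature oocytes, and over 237 tiles measured in all 6 libraries that took no part it had 70.8% against 79.1% to 82.1% (SD 1.24) in the other 5. DNA of other cells in the tube may explain it, since mitochondrial DNA took 1.12% of its calls against 20.2% to 63.4% in the other 7 kept oocyte libraries. Which cells these might be was not tested, nor was a biological difference between oocytes.

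The strands of a CpG disagreed at MspI sites in every group. In sperm the discordant share was 65.6% at these sites and 0.182% elsewhere, which argues against methylation of 1 strand in the cells as the cause in sperm. Cytosines filled in at the cut ends during library preparation may explain it, and counts without these CpGs are given with the other processing choices. The higher shares outside these sites in embryos are not covered by this test.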

How the results depend on the processing

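Leaving out CpGs on MspI sites, adding a lane term, leaving out Early morula 1, Early morula 2 and Compact morula 3, alone or with Compact morula 1, and the replicate block for the gamete classes were chosen after the result was seen. Among the alternatives run on comparison results, 264 kept the result. For a tile count this means a total within 1.5 times, and for the other results the direction and side of the threshold. The level differences of the 9 pairs have no exact p below 0.1, so for them only a change of direction could count against the result. A further 91 moved a tile count by more than 1.5 times, counts that fell to 0 included, and 14 reversed a direction. Apart from tile counts, 2 brought a difference past the threshold in the same direction and 10 ended a call. Those 10 all belonged to the drop from oocytes to 2-cell to 8-cell embryos. It kept its direction in all alternatives run, from -9.64 to -6.70 points without 1 library, but its adjusted p without 1 library reached 0.0821. Under the settings that left out no library its adjusted p lay between 0.00606 and 0.042. For the calls on named tiles, 663 of 1000 alternatives kept the call and 337 lost it. An alternative in which a tile could not be tested counts as neither. At 10 reads 60 of the 90 tiles were tested, without 2-cell 3 only 5 were and without Compact morula 2 only 4. A named call not given as lost was thus not always tested. Of 90 such calls, 71 were lost in the fit on the 2 groups alone and 64 with a lane term. Where a value below moved or reversed, the cause was not tested.

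For overall levels, oocytes minus sperm was -8.56 points at 1 read, 9.70 at 10 reads, 10.8 weighted by reads and -2.70 on shared tiles, and the first 3 passed the threshold, in opposite directions. In vivo MII oocytes minus sperm was -3.24 points at 1 read, and 4-cell minus 2-cell was -0.269 with all libraries. Without Early morula 1, Early morula 2 and Compact morula 3, morulae and blastocysts minus 2-cell to 8-cell embryos was -2.38 points and the change in sperm class minus oocyte class was 9.30 points, or 3.16 without Compact morula 1 as well. Without 1 library, the contrast of morulae and blastocysts ranged from -0.455 to 2.27 points and compact minus early morula from -2.07 to 4.67.

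Tile counts are given in the order of the comparisons, from In vivo MII oocyte against Immature oocyte to Blastocyst against Compact morula. At 1 read they were 1033, 2291, 9137, 6078, 19172, 5114, 990 and 2279. At 10 reads they moved to 161, 892, 8325, 1594, 178 and 418, all but the 2-cell and 4-cell comparisons, and to 5499 for In vivo MII oocyte against Sperm. With limma on tile percentages they moved to 258, 185, 1963, 7473, 73, 217 and 2287, all but the 2-cell comparison, and for In vivo MII oocyte against Sperm the 14222 calls turned to more falls than rises. With a lane term they were 7, 348, 1, 1901, 195, 1162, 4 and 146. Tiles of 100 bp gave 797 for In vivo MII oocyte against Immature oocyte, 801 for the compact morula and 1500 for the blastocyst comparison, and without CpGs on MspI sites the first and last of these were 746 and 2231. With no minimum difference, counts moved to 2321 for in vitro maturation, 5730 for 4-cell and 4207 for early morula. Without the 3 morula libraries, the early morula, compact morula and blastocyst comparisons gave 87, 222 and 386.

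Fitted on its 2 groups alone, the logistic test gave 0 tiles in 6 comparisons, with 7906 (immature), 4872 (in vitro), 14612 (2-cell), 13433 (4-cell), 4711 (compact morula) and 15031 (blastocyst) at an unadjusted p below 0.05 and 258, 185, 5793, 1963, 217 and 2287 calls by limma, and it gave 18 for Early morula against 8-cell.

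With the replicate number as a block, although the numbers do not pair the libraries, 42 of 90 calls on named tiles were lost and counts moved to 160 (immature), 1749 (4-cell), 6962 (8-cell), 923 (early morula), 109 (compact morula) and 176 (blastocyst).

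Without 1 library, counts ranged from 4107 to 12744 for In vivo MII oocyte against Sperm, 39 to 8221 against Immature oocyte, 153 to 5803 for in vitro against in vivo, 797 to 15110 for 2-cell, 1522 to 13152 for 4-cell, 3244 to 31613 for 8-cell, 135 to 5273 for early morula, 70 to 549 for compact morula and 3 to 1385 for blastocyst. A lone library left in a group was assumed to vary like the other groups, and tiles measured in it alone were then tested. These counts thus rest on different sets of tiles and do not show the effect of a library alone. Alternatives planned for promoters were not run. Depth limits the precision of single sites, with a median of 5 reads in sperm.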

Other observations

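The test on neighbouring tiles and the counts over other splits of the libraries were chosen before their result was seen. Early morula against 8-cell gave 2585 tiles and the highest of the other splits of the 6 libraries gave 426, so that 1 of 10 splits, the real one, gave as many. With 10 splits the design is too small for a share below 0.05. For Compact morula against Early morula, 9 of 10 splits gave as many tiles as the real 402, and the highest, 4269, set Compact morula 1, Compact morula 2 and Early morula 3 apart from the rest, which points to a structure of the samples other than stage. Again the splits are too few for a share below 0.05.

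Mitochondrial DNA took 20.2% to 63.4% of calls in oocytes other than In vivo MII oocyte 1, 25.1% to 33.1% in 2-cell embryos and 1.2% to 1.72% in 8-cell embryos. In early morulae 1, 2 and 3 it took 37.0%, 69.1% and 0.671%, and in compact morulae 28.4%, 18.8% and 56.4%. The 2 kept blastocysts had 0.490% and 0.914%. The 8-cell libraries, Early morula 3 and the kept blastocysts, all at or below 1.72%, had mean CpG levels of 13.9% to 16.6%. Every other kept embryo library, at 8.51% or more, had a level of 21.4% to 33.4%. The low levels at the 8-cell stage and in blastocysts thus coincide with this split, whose bearing on the level was not tested. Sites of intermediate level (20% to 80% of thinned reads) made up 30.1% to 32.1% of sites in 8-cell embryos, 27.4% in Early morula 3 and 33.5% in Blastocyst 2, against 10.4% in Blastocyst 1, 15.6% in In vivo MII oocyte 1 and 3.5% to 5.4% in the other kept oocyte libraries.

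Tiles methylated in oocytes and not in sperm were searched for marks held near the middle of the scale from the 8-cell stage on. In 47 of 1521 such tiles the level lay between 35% and 65% in each of 5 libraries, 8-cell 1 to 3 and both kept blastocysts, against 0 of 8107 sperm-methylated tiles. The sperm class averaged only 11.6% in 8-cell embryos and 15.5% in blastocysts, in classes set on all oocyte groups. Its count of 0 thus largely follows from the class means and does not bear on kept marks. The 47 tiles neighboured each other in 2 pairs against 0.3 in random draws of the class (permutation p 0.0372). The draws did not allow for likeness between neighbouring tiles, so this count cannot tell whether marks were kept as stretches. The mean of the oocyte class also lies close to the range searched. The pairs spanned chromosome 7, 12416401 to 12417000, and chromosome 27, 23706901 to 23707500, with 8-cell levels of 40.4% and 48.6%, blastocyst levels of 47.7% and 46.7%, and levels of 48.9% and 16.8% in Early morula 3.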
